A study of Mus musculus with 8 samples.

How the data were processed

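The submitters' notes name cutadapt 2.10, STAR 2.7.5c and RSEM 1.3.3 for read trimming, alignment and quantification, Cell Ranger 6.1.1 and Seurat 4.0.2 for the droplet data, and the mouse build mm10, without settings. The bulk values were TPM, read shares corrected for transcript length and scaled by the authors, for 55413 genes, and each library's column summed to 1000000. The droplet values were whole-number UMI counts for 15083 genes seen in at least 3 cells, in 9076 cells that the authors kept, and the summed counts of all 9076 cells equalled the totals in the cell table. Each cell carried the authors' hashtag, treatment and cluster number. How the authors treated doublets is not given in the sources used here, and no doublet caller was run. Every cell kept had a single hashtag, but 2 cells of the same hashtag in a droplet would not be seen, and cells with very many UMIs were left out only in the alternative between the 10th and 90th percentile. The percent of a cell's UMIs in mitochondrial DNA-encoded genes was computed by the authors, as deposited in the cell table, and reached at most 7.50% after their filter. Gene symbols were matched to GENCODE M21 on GRCm38 (mm10), which gave coordinates for 53253 bulk and 14870 single-cell symbols.

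Bulk genes were tested with limma 3.58.1 on log2(TPM + 1), with an expression-dependent prior variance (trend), treatment as the sole term, and Benjamini-Hochberg adjustment over the 11222 genes with TPM of at least 1 in at least 3 of the 6 libraries. A gene passed at an adjusted p under 0.05. The labels do not say that replicate numbers mark a shared mouse or day, and the correlations of equally numbered libraries after removal of the group means were 0.0186, -0.0710 and -0.00177, so no pairing was fitted. Fold changes are dopamine over its control, and IL-33 over PBS where that comparison is named. In the bulk data they are also given relative to the median of all tested genes, because the deposited TPM put that median at 0.49 (log2), where median-of-ratios scaling put it at 0.05. Counts of members without overlap, or passing adjusted over the list alone, rest on the deposited TPM and so favour higher members. Where another setting or a library left out moved the relative change of a named gene by over 1.5 times, its range over all of these follows the value. For genes that turned in sign, such as CT010467.1, single settings are named instead of the full range.

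Hashtag counts were summed over cells and tested with edgeR 4.0.16 (TMM, quasi-likelihood), IL-33 plus dopamine (hashtags 6, 7 and 8) against IL-33 (hashtags 3, 4 and 5), over 10559 genes kept by filterByExpr. Levels are given as UMI counts scaled to a hashtag total of 1000000 (CPM). Each hashtag was treated as 1 replicate; the labels do not state that it was 1 mouse. The same test ran within each of the 6 clusters. DESeq2 1.42.0 served as an alternative, and all tests ran in R 4.3.3. Single values per library and cluster shares were compared with exact two-sided permutation tests, for which 3 against 3 replicates give no p under 0.1.

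A total of 41 gene lists, 28 functional and 13 of cell type markers, were tested with camera at a preset inter-gene correlation of 0.01, two-sided, and adjusted over the lists with at least 3 tested members. Functional lists covered complex I, complexes II and III, complex IV, complex V, mitochondrial DNA-encoded subunits, mitochondrial ribosome, mitochondrial import and dynamics, TCA cycle, glycolysis, and fatty acid uptake and oxidation. Further functional lists covered type 2 effectors, ILC2 identity, proliferation, catecholamine receptors, cAMP and CREB response, immediate early and dissociation response, NF-kB response, and interferon response. The last covered cytosolic ribosome, proteasome, unfolded protein response, NRF2 response, hypoxia response, p53 response, MYC and mTORC1, cholesterol synthesis, inhibitory and co-stimulatory receptors, and migration. Marker lists covered T cells, B cells, NK cells and ILC1, ILC3, macrophages, neutrophils, eosinophils, basophils and mast cells, dendritic cells, lung epithelium, endothelium, fibroblasts, and erythroid cells. The camera calls were recomputed with a correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, in a single direction. No camera call of any of the comparisons held with the estimated correlation.

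The lists, the tests, the filters and the rule for naming genes were chosen before the data were examined. By that rule, the bulk text names up to 12 passing genes per direction with TPM of at least 10 and no overlap between groups, filled up to 6 with genes that did not pass. It also names up to 4 members of each functional list that passed with the smallest p, and 16 fixed genes, of which 1 is not reported here. The single-cell text names up to 10 genes per direction with CPM of at least 50 and the same sign in all clusters, passing genes first. Genes with predicted or clone-based names fell outside the rule, so Gm10801 and CT010467.1 were chosen after their values were seen. So were the members named for the marker lists, for the single-cell lists, within clusters and for IL-33 against PBS, a comparison added after the data were seen.

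Simulated data with the same numbers of samples measured what the tests could recover. Genes were drawn independently of each other, without shifts shared across a library, so false calls from such shifts were not measured. In the bulk design, 5 of 100 genes changed 2-fold and 23 of 100 changed 4-fold were recovered, with 0 false calls. In the single-cell design, 46 of 100 genes changed 1.5-fold and 85 of 100 changed 2-fold were recovered, with 7 false calls among 10428 genes; for IL-33 against PBS the numbers were 43 and 67 of 100, with 4 false calls among 10353.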

Results

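Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that lack antigen receptors and release type 2 cytokines when the epithelial alarmin IL-33 reaches them. Lung ILC2s were sorted from wild type C57BL/6 mice that had received IL-33 through the nose for 3 days together with either dopamine, a catecholamine neurotransmitter, or its vehicle PBS. Full-length RNA libraries (Smart-Seq2) were made in bulk from 2000 cells each, 3 from female mice given IL-33 plus PBS and 3 from female mice given IL-33 plus dopamine. Their values carry no read counts, so the sequencing depth behind them is unknown. The number of genes with TPM of at least 1 was 11384, 9822 and 10525 in PBS libraries 1 to 3 and 11502, 11529 and 11745 in dopamine libraries 1 to 3.

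A droplet (10x) pool from male mice held 8 antibody hashtags. The cell table assigns hashtags 1 and 2 to PBS without IL-33 (311 and 748 cells), hashtags 3, 4 and 5 to IL-33 (1485, 1092 and 1516 cells) and hashtags 6, 7 and 8 to IL-33 plus dopamine (1252, 1197 and 1475 cells). Total UMIs per hashtag ran from 1397576 in hashtag 1 to 9268932 in hashtag 3, and the median cell held between 4201 UMIs in hashtag 8 and 5692 in hashtag 3. Gata3, the transcription factor that defines the lineage, had a UMI in 89.9% of IL-33 cells and 89.98% of IL-33 plus dopamine cells, and Il1rl1, the IL-33 receptor, in 92.1% and 92.6%. Lyz2, an abundant myeloid transcript, had a UMI in 0.269% and 0.255% of the cells, which gives the level of free RNA or rare other cells.

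The bulk comparison asked what dopamine does to the transcriptome of IL-33-activated lung ILC2s, and in particular to the genes behind mitochondrial activity, the process named in the title of the series. Genes of the respiratory chain, of mitochondrial and cytosolic ribosomes, of the proteasome and of the cell cycle were lower as groups with dopamine than with PBS. Genes of the cAMP and NF-kB lists, immediate early genes and genes that guide migration were higher as groups. Transcripts typical of T cells, NK cells and ILC3s were higher too. Single genes seldom passed the adjustment over the genome, and the type 2 cytokine genes did not pass.

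By limma, 4 of 11222 genes passed, all higher with dopamine, and 2706 had an unadjusted p under 0.05. Of those 2706, 2188 were higher and 518 lower in the deposited TPM, but the balance turned over with scaling: median-of-ratios scaling gave 1065 higher and 1453 lower, and quantile normalization 1095 and 1247. Genes that passed turned likewise, from 4 higher and 0 lower to 2 higher and 3 lower with median-of-ratios scaling and 10 higher and 11 lower with quantile normalization. Camera placed 20 of 38 lists past the threshold, 13 lower and 7 higher, and 18 did not pass. PBS library 2 stood apart, with the fewest genes and a first principal component score of -99.4 against -46.9 to 62.5 in the others; without it, limma passed 0 genes (1569 at an unadjusted p under 0.05) and camera 20 lists, as an alternative given first rank after the data were seen. The gene count also moved to 1536 without PBS library 1, to 90 without PBS library 3 and to 1 without dopamine library 2. No list passed with an estimated correlation or with fry.

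Of the 4 genes, 2 were T cell receptor segments. Trav11d (chr14:52824357-52824912) and Trbv13-2 (chr6:41121396-41121832) are variable segments of the T cell receptor alpha and beta chains, a pair typical of natural killer T cells. Trav11d was listed at 0 in all 3 PBS libraries and at 15.96, 79.49 and 21.26 TPM with dopamine (adjusted p = 0.0426), and Trbv13-2 at 0 and at 16.26, 32.36 and 10.82 TPM (adjusted p = 0.0426). Gm10801 (chr2:98662237-98664083), a predicted gene, stood at 40.66, 117.38 and 146.4 TPM with PBS and rose to 3666, 3144 and 1528 TPM with dopamine (log2 fold change 4.86 ± 0.46 SE, adjusted p = 0.0091). CT010467.1 (chr17:39846353-39848827), a ribosomal RNA gene, took 3.71% ± 0.28 (SD, n = 3) of all TPM with PBS and 5.81% ± 0.274 with dopamine (adjusted p = 0.0426 by limma). Its fold change relative to all genes was 0.15, and this turned to -0.02 with quantile normalization and to -0.04 without PBS library 1. These are the settings that turned its sign, and leaving out another library raised it.

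Nuclear genes of the respiratory chain, which oxidises NADH and succinate and makes ATP, were lower as lists. Over the 79 genes of the 4 lists pooled, the mean relative to all genes differed by -0.94 (95% interval -1.65 to -0.24), and by -0.41 (-0.88 to 0.05) with the number of detected genes as a covariate, an alternative chosen after the data were seen. The pooled mean was highest in PBS library 2 (4.960, against 4.135 and 4.397 in PBS libraries 1 and 3). Quantile normalization and the removal of trends with length, GC content and expression kept the 4 calls with smaller medians, given in that order after each list. Complex I, the entry point for NADH, had a median of -1.04 relative to all genes, with 34 of 36 members lower in mean TPM (adjusted p = 1.8e-19; adjusted p = 0.222 with an estimated correlation; medians -0.657 and -0.564). The groups did not overlap for 23 of the 36, where interchangeable libraries would give 10%. The share over all tested genes is not given here, and lists that did not pass also held such members. Glycolysis had 6 of 18 lower and 1 higher without overlap, and ILC2 identity 9 of 24 higher and 2 lower. Over all genes 0 of the 36 passed, and adjusted over the list alone 11 passed, all lower. Ndufa11 went from 283 ± 58.7 to 130 ± 13.9 TPM (relative log2 fold change -1.60, range -1.74 to -0.99), Ndufb9 from 275 ± 33.3 to 146 ± 7.3 TPM (-1.39, range -1.56 to -0.67) and Ndufc2 from 143 ± 25.6 to 57.1 ± 19 TPM (-1.85, range -2.07 to -1.19). Complex V, the ATP synthase, had all 17 members lower and a median of -1.04 (adjusted p = 1.3e-12; 0.222 with an estimated correlation; medians -0.552 and -0.629), 11 without overlap and 10 passing adjusted over the list alone. Atp5e went from 758 ± 261 to 324 ± 89.6 TPM (-1.69). Complex IV, cytochrome c oxidase, had a median of -1.02 (adjusted p = 1.4e-08; 0.222 with an estimated correlation; medians -0.594 and -0.340). In it, 8 of 12 members were lower without overlap and 7 passed adjusted over the list alone. Cox8a went from 1389 ± 216 to 855 ± 82 TPM (-1.19, range -1.47 to -0.36) and Cox5a from 519 ± 79.5 to 301 ± 52.7 TPM (-1.28, range -1.49 to -0.83). Complexes II and III had a median of -0.92 (adjusted p = 3.6e-06; 0.222 with an estimated correlation; medians -0.515 and -0.479), with 6 of 14 lower without overlap, among them Uqcrq and Sdhb, and 0 passing adjusted over the list alone.

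Mitochondrial protein synthesis and import moved with the respiratory chain. The mitochondrial ribosome list had a median of -0.87, with 45 of 51 members lower, 13 without overlap and 1 passing adjusted over the list alone (adjusted p = 5.8e-13; 0.222 with an estimated correlation). Mrps12, a small-subunit protein at chr7:28739641-28741820, went from 127 ± 34.6 to 42.1 ± 4.75 TPM (-2.04), and Mrpl36 from 83.8 ± 13 to 38.1 ± 7.84 TPM (-1.62, range -1.78 to -1.06). Import and dynamics genes had a median of -0.81 (adjusted p = 0.00018; 0.39 with an estimated correlation) but went both ways. That median was -0.524 without PBS library 2, -0.518 without a filter, -0.489 with quantile normalization and -0.398 with trends removed. Without overlap, 7 were lower, such as Tomm5 (-1.34, range -1.56 to -0.68) and the fission factor gene Fis1 (-1.06, range -1.21 to -0.43), and 4 higher, such as the inner membrane fusion gene Opa1 (relative log2 fold change 1.51, range 0.88 to 2.04). Subunits encoded in mitochondrial DNA had a median of -0.74 with 1 of 11 lower without overlap (adjusted p = 0.00064; 0.39 with an estimated correlation), and this call was lost with quantile normalization (median -0.0831) and once trends with length, GC content and expression were removed (median -0.284, adjusted p = 0.25). Their share of TPM was 2.91% ± 0.375 with PBS and 2.31% ± 0.439 with dopamine (n = 3 each, exact permutation p = 0.2). The difference of -0.600 percentage points was -0.364 without dopamine library 3. Fatty acid uptake and oxidation genes had a median of -0.54 (adjusted p = 0.0197; 0.747 with an estimated correlation), and this call was lost without PBS library 1 (0.285) or dopamine library 3 (0.0649) and with array weights (median -0.526); the median was -0.353 with a pseudocount of 5. Pparg, the gene of a lipid-sensing receptor, stood at 63.6 ± 29.6 TPM with PBS and 29.1 ± 8.09 TPM with dopamine. Dgat1, which makes triglycerides, went the other way from 386 ± 316 to 958 ± 82.4 TPM. The TCA cycle (adjusted p = 0.318), glycolysis (0.265) and hypoxia (0.193) lists did not pass.

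**Figure D1:**
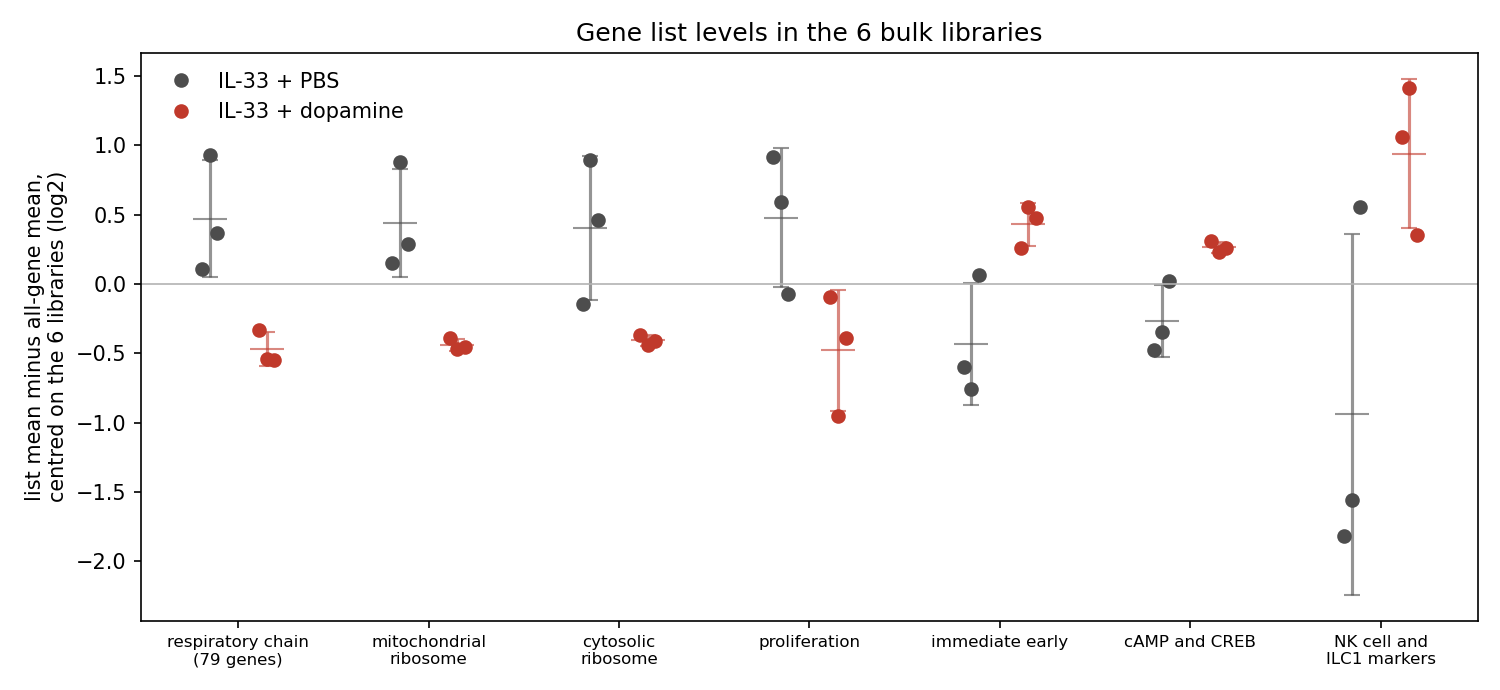
Mean log2(TPM + 1) of each gene list minus the mean of all genes, centred on the 6 libraries, with a point per library and bars for the mean and SD of 3 libraries per group. The respiratory chain, 79 genes of 4 lists pooled, was lower in the 3 dopamine libraries by 0.94 on average, and the NK cell and ILC1 markers overlapped between the groups in PBS library 3.

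Growth and division genes were lower. Cytosolic ribosome genes had a median of -0.82, with 68 of 70 members lower, 48 without overlap and 30 passing adjusted over the list alone (adjusted p = 1.4e-37; 0.349 with an estimated correlation). Quantile normalization brought that median to -0.105 and the removal of length, GC and expression trends to -0.232, and the call stayed. The mean of the list relative to all genes differed by -0.81 (95% interval -1.65 to 0.03), and by -0.15 (-0.44 to 0.14) with the number of detected genes as a covariate. Rpl28 (chr7:4792874-4795066) went from 3624 ± 426 to 1915 ± 226 TPM (-1.41, range -1.66 to -0.72, adjusted p = 0.068) and Rps26 (chr10:128624534-128626747) from 3362 ± 527 to 1863 ± 89.6 TPM (-1.34, range -1.58 to -0.63). The list took 31.0% ± 3.68 of TPM with PBS and 24.9% ± 0.652 with dopamine (n = 3 each, exact permutation p = 0.1). The proteasome, which degrades proteins marked with ubiquitin, had a median of -0.78 with 12 of 36 members lower without overlap and 0 passing adjusted over the list alone (adjusted p = 5.5e-09; 0.222 with an estimated correlation), and a median of -0.374 with quantile normalization and -0.366 with trends removed. Psma1 went from 318 ± 42.4 to 193 ± 29 TPM. Proliferation genes had a median of -0.72 with 8 of 35 members lower without overlap and 4 passing adjusted over the list alone (adjusted p = 1.5e-07; 0.544 with an estimated correlation; median -0.430 with array weights). The mitotic cyclin Ccnb2 went from 64.8 ± 27 to 14.7 ± 6.19 TPM (-2.53), the ubiquitin ligase component Ube2c from 95.1 ± 19.8 to 30.3 ± 15.7 TPM (-2.21). Birc5, which encodes survivin, went from 80.4 ± 25.4 to 22.2 ± 13.6 TPM (-2.40) and the microtubule regulator Stmn1 from 241 ± 90.1 to 80.4 ± 32.6 TPM (-2.07). Mki67, the usual proliferation marker, stood at 4.49 ± 3.48 TPM with PBS and 4.7 ± 1.84 TPM with dopamine and did not pass (adjusted p = 0.867).

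The cAMP, immediate early and NF-kB lists were higher. The cAMP and CREB list, the transcripts that cyclic AMP induces, had a median of 0.49, with 15 of 17 members higher without overlap and 13 passing adjusted over the list alone (adjusted p = 0.00011; 0.39 with an estimated correlation), and a median of 0.304 without PBS library 1 and 0.274 with array weights. Nr4a1, an orphan nuclear receptor, went from 605 ± 320 to 1904 ± 447 TPM (1.33), the AP-1 subunit Fosl2 from 27.1 ± 11.6 to 80.4 ± 4.75 TPM (1.14). The phosphatase gene Dusp1 went from 957 ± 396 to 2204 ± 368 TPM (0.78, range 0.32 to 1.39) and the CREB family member Crem from 450 ± 83.7 to 779 ± 76.9 TPM (0.31, range 0.12 to 0.78, and 0.16 without PBS library 1). Dusp1 also belongs to the immediate early list, so the cAMP and immediate early lists are not independent. A cAMP signal was not separated from a response to the handling of the cells. The immediate early list, which tissue dissociation also induces, had a median of 0.79 with all 22 members higher, 16 without overlap and 17 passing adjusted over the list alone (adjusted p = 4.9e-09; 0.39 with an estimated correlation; median 0.522 with array weights). Fosb went from 37.8 ± 18.8 to 196 ± 41.8 TPM (1.99), Zfp36, which destabilises cytokine mRNAs, from 169 ± 82 to 586 ± 103 TPM (1.43), and Egr1 from 111 ± 41.3 to 314 ± 36.3 TPM (1.07). NF-kB targets had a median of 0.66, with 7 of 18 members below the median of all genes. In the deposited TPM 10 were higher and 1 lower without overlap, and 10 higher and 1 lower passed adjusted over the list alone. The list passed by camera (adjusted p = 0.038, and 0.747 with an estimated correlation). This call was lost without PBS library 1 (adjusted p = 0.127) or dopamine library 3 (0.0894), and the median was 0.405 without PBS library 2. It was also lost with array weights (median 0.325), median-of-ratios scaling (0.566), a mean TPM of at least 5 (0.680) and rescaling without mitochondrial DNA-encoded and cytosolic ribosome genes (0.614). Tnfaip3, which shuts NF-kB down, went from 205 ± 152 to 848 ± 114 TPM (1.82) and Tnf from 41.3 ± 21.5 to 122 ± 14.3 TPM (1.19, range 0.65 to 1.58).

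The migration list was higher, and the inhibitory receptor and NRF2 lists were lower. Migration and residency genes had a median of 0.43, with 9 of 22 members below the median of all genes. In the deposited TPM 14 were higher without overlap, and 10 passed adjusted over the list alone. The list passed by camera (adjusted p = 0.00074, and 0.544 with an estimated correlation). The median was 0.12 without dopamine library 1 and 0.217 without dopamine library 2. It was 0.660 without a filter, 0.241 at a mean TPM of at least 5, 0.276 with trends removed and 0.0638 with array weights, where the call was lost. S1pr1, which leads lymphocytes out of tissue, went from 18.5 ± 12.3 to 101 ± 29.9 TPM (2.17). The chemokine receptor gene Cxcr3 went from 4.16 ± 6.86 to 37.1 ± 15.7 TPM (3.27, range 1.51 to 4.77) and Itgae, the integrin that holds cells to epithelium, from 18.8 ± 16.8 to 75.6 ± 7.22 TPM (1.82). In the single cells the migration list had a median of 0.03 and did not pass (adjusted p = 0.771 by camera). Whether ILC2s or other lymphocytes among the sorted cells carried these transcripts in bulk was not tested. Inhibitory and co-stimulatory receptors had a median of -0.62, with 4 of 16 lower and 3 higher without overlap and 2 passing, both lower, adjusted over the list alone (adjusted p = 0.0128; 0.606 with an estimated correlation; 0.0766 without PBS library 1). This call was also lost without a filter (median -0.272) and with trends removed (-0.400), and the median was -0.412 with a pseudocount of 5. Pdcd1, the gene of PD-1, went from 354 ± 57.8 to 201 ± 18.5 TPM (-1.30, range -1.40 to -0.85). Tnfrsf4, the gene of OX40, went from 106 ± 49.9 to 24.4 ± 18 TPM (-2.84) and Ctla4 from 105 ± 50.4 to 43 ± 23.3 TPM (-1.78). Cd274, the PD-1 ligand gene, was higher at 8.29 ± 3.94 TPM with PBS and 21.8 ± 0.73 TPM with dopamine. The NRF2 list, the defence against oxidants, tested lower (adjusted p = 0.029; 0.39 with an estimated correlation) with a median of -0.42 relative to all genes, although its median in the deposited TPM was 0.07. This call was lost without PBS library 3 (adjusted p = 0.0716) or dopamine library 1 (0.103, median -0.244), and with no filter (median -0.177), quantile normalization (-0.106) or trends removed (0.0177); the median was -0.220 with a pseudocount of 5. Its redox genes Mt2 (-2.46) and Txn1 (-1.52, range -1.67 to -0.94) were lower without overlap.

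Markers of NK cells, ILC3s and T cells were higher. NK cell and ILC1 markers had a median of 2.12, with 5 of 8 members higher without overlap and 7 passing adjusted over the list alone (adjusted p = 0.00118; 0.544 with an estimated correlation). That median was 1.28 with a pseudocount of 5 and 0.744 with array weights, where the NK, ILC3 (0.914) and T cell (0.245) calls were lost. Gzma, a cytotoxic protease gene, went from 10.2 ± 8.51 to 92.2 ± 34.9 TPM (2.83, range 1.85 to 3.45). The activating receptor gene Klrk1 went from 30.9 ± 38.1 to 174 ± 36.7 TPM (2.67, range 1.11 to 3.70), and Tbx21, the factor that directs type 1 lymphocytes, from 2.26 ± 2.39 to 16.9 ± 9.5 TPM (2.07, range 1.05 to 2.77). ILC3 markers had a median of 1.52, with 8 of 10 higher and 1 lower without overlap (adjusted p = 0.00916; 0.544 with an estimated correlation; 0.285 without PBS library 1) and 8 higher and 1 lower passing adjusted over the list alone. The lower one was Ltb4r1, a leukotriene receptor gene, which went from 428 ± 85.4 to 203 ± 39.9 TPM (-1.57). T cell markers had a median of 0.43 with 3 of 8 higher without overlap and 4 passing adjusted over the list alone (adjusted p = 0.029; 0.689 with an estimated correlation). This call was lost without PBS library 1 (adjusted p = 0.352) or dopamine library 2 (0.232, median 0.166), and the median was 0.674 without dopamine library 1, 0.664 without a filter, 0.721 with quantile normalization and 2.43 at a mean TPM of at least 5. Cd3e stood at 4.33, 6.68 and 43.59 TPM with PBS and at 44.75, 170.39 and 104.76 TPM with dopamine. PBS library 3 held more of these transcripts than the other PBS libraries. Markers of B cells (adjusted p = 0.443), macrophages (0.686), eosinophils (0.466), basophils and mast cells (0.723), dendritic cells (0.607), lung epithelium (0.542) and endothelium (0.986) did not pass, and the neutrophil, fibroblast and erythroid lists had too few members above the filter to be tested.

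The effector programme of ILC2s did not pass. The type 2 effector list (adjusted p = 0.686) and the ILC2 identity list (0.466) did not pass. Il5, which feeds eosinophils, stood at 544 ± 134 TPM with PBS and 483 ± 216 TPM with dopamine (adjusted p = 0.646). Il13, which drives mucus production, stood at 30.7 ± 1.81 TPM with PBS and 24.6 ± 4.84 TPM with dopamine (adjusted p = 0.548) and the repair factor gene Areg at 1047 ± 97.3 TPM with PBS and 872 ± 262 TPM with dopamine (adjusted p = 0.386). Gata3 (adjusted p = 0.808) and Il1rl1 (0.715) did not pass either. Arg1, which breaks down arginine, stood at 851 ± 364 TPM with PBS and 354 ± 171 TPM with dopamine without overlap (relative log2 fold change -1.79, adjusted p = 0.101). The activation marker Klrg1 stood at 333 ± 86.8 TPM with PBS and 201 ± 72.8 TPM with dopamine (adjusted p = 0.167). Arg1 and Klrg1 did not pass, nor did mt-Co1 (adjusted p = 0.333) and Ndufa4 (0.562). Of the dopamine receptor genes, Drd1, Drd2, Drd3 and Drd5 were listed at 0 in all 6 libraries and Drd4 at 0.22 TPM in PBS library 2 only. The catecholamine (adjusted p = 0.896), interferon (0.635), unfolded protein (0.677), p53 (0.443), MYC and mTORC1 (0.466) and cholesterol synthesis (0.629) lists did not pass. Test and relative median differed in sign for the catecholamine list (lower, 0.24), the ILC2 identity list (higher, -0.07), the interferon list (higher, -0.03) and the dendritic cell list (higher, -0.17).

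Other genes outside these lists missed the threshold and did not overlap between the groups. Cd163l1 (chr7:140218267-140231145), a scavenger receptor gene of gamma delta T cells, went from 8.53 ± 7.03 to 183 ± 104 TPM (3.81, adjusted p = 0.0517). Lncpint (chr6:31082565-31220488), a long noncoding RNA induced by p53, went from 35.7 ± 9.45 to 154 ± 21.1 TPM (1.61, adjusted p = 0.0517). The clock repressor gene Nr1d2 went from 2.88 ± 1.36 to 27.8 ± 0.967 TPM (2.45) and Syne2, which links nucleus and cytoskeleton, from 2.04 ± 1.37 to 23.9 ± 4.14 TPM (2.61). On the lower side, Lgals1 (chr15:78926725-78930465), the galectin-1 gene, went from 2971 ± 434 to 1661 ± 82.4 TPM (-1.32, range -1.59 to -0.56, adjusted p = 0.0703). The snoRNA host Snhg3 went from 52.7 ± 21.2 to 5.68 ± 5.11 TPM (-3.70). The retinoic acid carrier gene Crabp2 stood at 12.2 ± 10.4 TPM with PBS and was listed at 0 in all 3 dopamine libraries.

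**Figure D2:**
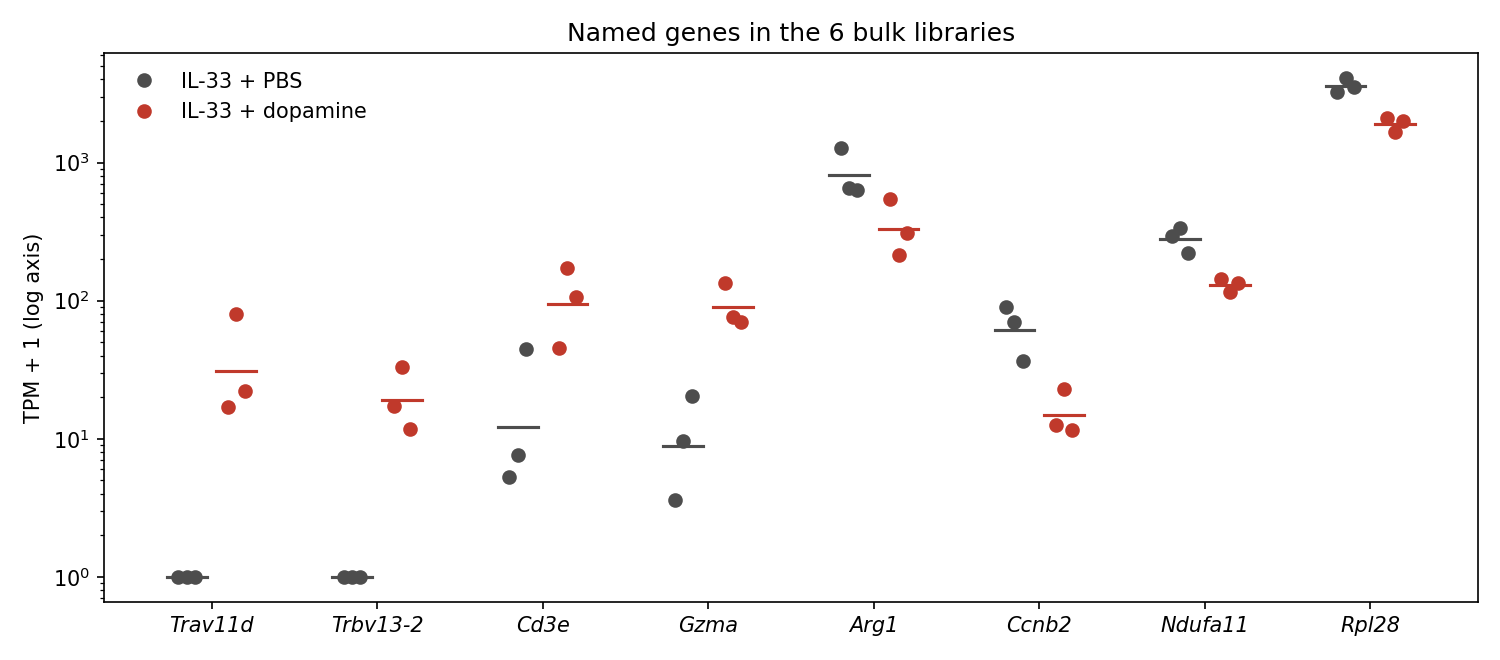
TPM + 1 of named genes on a log axis, with a point per library and a line at the mean of the log values of 3 libraries per group. Trav11d and Trbv13-2 were listed at 0 in all PBS libraries, and Arg1, Ccnb2, Ndufa11 and Rpl28 were lower in each dopamine library than in each PBS library.

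In the single cells, dopamine under IL-33 was tested in other mice with the same question. Cd3g and Actn2, the leading genes of cluster 1, and the leukotriene receptor gene Ltb4r1 fell. T cell signalling genes, mitochondrial and cytosolic ribosome genes, cell cycle genes and lipid genes were lower as lists, and cAMP, immediate early, NF-kB and MYC genes were higher. Respiratory chain lists did not pass, and their members differed little. Of the 33 lists tested in both experiments, 30 had a median closer to 0 in the single cells than in bulk; the T cell list did not.

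By edgeR, 3 of 10559 genes passed, all lower with dopamine, and 1000 had an unadjusted p under 0.05 (508 higher, 492 lower); DESeq2 passed 27, 12 higher and 15 lower. Without hashtag 8, whose profile lay apart from the other IL-33 hashtags, 2 genes and 9 lists passed, an alternative put forward after the data were seen. The gene count moved to 1 without hashtag 3, 1 without hashtag 4, 7 without hashtag 6 and 16 without hashtag 7. Cd3g (chr9:44969572-44980431), a chain of the T cell receptor complex that ILC2s also transcribe, fell from 103 ± 9.92 to 49.2 ± 4.06 CPM (log2 fold change -1.07 ± 0.10 SE, adjusted p = 0.0014), against 61.9 CPM in PBS hashtags. Actn2 (chr13:12269426-12340760), an actin crosslinker gene, fell from 43.2 ± 2.81 to 19.3 ± 3.88 CPM (-1.16 ± 0.13 SE, adjusted p = 0.00895), against 28.3 CPM. Ltb4r1 (chr14:55765962-55768494) fell from 310 ± 16 to 206 ± 21.6 CPM (-0.59 ± 0.08 SE, adjusted p = 0.0293), against 208 CPM. None of the 3 genes overlapped between the hashtags of the groups. With clusters weighted equally only Cd3g passed, and Actn2 (-0.80) and Ltb4r1 (-0.43) did not. That setting averaged log2 CPM over the clusters, with a small count added, and tested it by limma. Changes of genes with few UMIs shrink in it whatever the cluster shares. Actn2 also missed the threshold without hashtag 3 (-1.132) or 4 (-1.130), and Ltb4r1 without hashtag 3 (-0.583), 4 (-0.629), 5 (-0.553) or 8 (-0.537).

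Camera placed 9 of 34 lists past the threshold, 5 lower and 4 higher, of which 0 held with an estimated correlation and 1, the T cell list, with fry (adjusted p = 0.0267). With clusters weighted equally 3 passed, the T cell, cytosolic ribosome and NF-kB lists. For the other 6 a shift of cells between clusters, the shrinkage of low counts in that setting and a change within cells were not separated. The T cell list had a median of -0.45 (adjusted p = 1.5e-05; 0.229 with an estimated correlation; median -0.26 without hashtag 7, -0.680 in thinned cells and -0.229 at a minimum of 20 UMIs), 2 of 5 members passing adjusted over the list alone. Cd3e went from 6.47 ± 1.79 to 3.14 ± 1.11 CPM (-1.01, or -0.62 with clusters weighted equally) and Cd3d from 3.29 ± 0.0721 to 2.41 ± 0.575 CPM (-0.45, or -0.68 in thinned cells and -0.26 without hashtag 7). Mitochondrial ribosome genes had a median of -0.09 with 41 of 51 members lower (adjusted p = 0.00019; 0.814 with an estimated correlation; median -0.144 without hashtag 4 and -0.0404, not passing, with clusters weighted equally), and Mrpl34 went from 39.1 ± 4.83 to 24.8 ± 4.47 CPM (-0.66). Proliferation genes had a median of -0.08 with 19 of 25 lower and 4 passing adjusted over the list alone (adjusted p = 0.0032; 0.469 with an estimated correlation). This call was lost without hashtag 6 (adjusted p = 0.0885), and the median was -0.241 without hashtag 5 and -0.127 without hashtag 7. It was also lost with clusters weighted equally (median -0.0398, adjusted p = 0.163), in cells between the 10th and 90th percentile of UMIs (-0.0412), in thinned cells (-0.108) and as a mean over cells (-0.0726). Ccnb2 went from 6.29 ± 0.398 to 2.18 ± 1.29 CPM (-1.51, or -0.55 with clusters weighted equally and -0.90 as a mean over cells). Cenpe, a kinetochore motor gene, went from 5.92 ± 1.83 to 1.73 ± 1.15 CPM (-1.78, or -0.36 and -0.86) and Stmn1 from 23.9 ± 1.78 to 15.4 ± 1.11 CPM (-0.62, or -0.37 with clusters weighted equally and -0.34 in the middle percentiles). Fatty acid genes (median -0.11, adjusted p = 0.0389; 0.63 with an estimated correlation) included Plin2, the coat protein of lipid droplets, at from 86.1 ± 6.67 to 58.6 ± 14.9 CPM. The fatty acid call was lost without hashtag 3, 5, 6 or 7 (adjusted p = 0.0576, 0.19, 0.272 and 0.0566). It was also lost as a mean over cells (median -0.0955), in the middle percentiles (-0.0670), in thinned cells (-0.104), with clusters weighted equally (-0.0860), at a minimum of 20 UMIs (-0.108) and without cluster 4 (-0.141). Cytosolic ribosome genes had a median of -0.04 (adjusted p = 0.0394; 0.873 with an estimated correlation), and this call was lost without hashtag 3, 4, 5, 6 or 7 (adjusted p = 0.0726, 0.0598, 0.224, 0.208 and 0.16) or without cluster 4 (median -0.0395).

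The higher lists were NF-kB targets, MYC and mTORC1 genes, cAMP response genes and immediate early genes. NF-kB targets had a median of 0.15 with 16 of 18 members higher, and 3 higher and 1 lower passing adjusted over the list alone (adjusted p = 0.0099; 0.814 with an estimated correlation). This call was lost without hashtag 4, 5 or 7 (adjusted p = 0.0778, 0.0872 and 0.0657), and the median was 0.235 without hashtag 6, 0.0737 without hashtag 7 and 0.0948 without hashtag 8. The inhibitor gene Nfkbid went from 243 ± 7.75 to 311 ± 32.8 CPM (0.36) and Tnfrsf9, the gene of 4-1BB, went from 24.1 ± 2.71 to 34 ± 6.14 CPM (0.51, or -0.01 with clusters weighted equally). MYC and mTORC1 genes had a median of 0.08 with 1 passing adjusted over the list alone (adjusted p = 0.0066; 0.718 with an estimated correlation; median 0.0454 without hashtag 8). This call was lost with clusters weighted equally (median 0.0391) and in the middle percentiles of UMIs (0.0598). Its leading gene Odc1, the gate to polyamine synthesis, went from 494 ± 50.9 to 803 ± 173 CPM (0.71, or 0.42 with clusters weighted equally). The cAMP list had a median of 0.11 (adjusted p = 0.0262; 0.873 with an estimated correlation), with Crem at from 195 ± 15.9 to 253 ± 53.3 CPM (0.38, or 0.10 with clusters weighted equally) and Nr4a3 at from 338 ± 28 to 448 ± 86.5 CPM (0.42, or 0.25); without hashtag 8 these were 0.19 and 0.22. The cAMP call was lost without hashtag 4 (adjusted p = 0.189) or 8 (0.867, median 0.0324), and the median was 0.198, 0.194 and 0.17 without hashtags 5, 6 and 7. It was also lost with clusters weighted equally (median 0.0128), and the median was 0.186 in the middle percentiles and 0.165 in thinned cells. The immediate early list had a median of 0.09 (adjusted p = 0.0262; 0.873 with an estimated correlation), which turned to -0.02 without hashtag 8 (adjusted p = 0.969) and was 0.141 without hashtag 6 and 0.227 without hashtag 7; the call was also lost without hashtag 3 (adjusted p = 0.111), in the middle percentiles (median 0.130) and with clusters weighted equally (0.0615), and the median was 0.163 without cluster 4.

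Lists that did not pass included complex I with a median of -0.003 (adjusted p = 0.741), complexes II and III (0.247), complex IV (0.247), complex V (0.338), mitochondrial DNA-encoded subunits (0.546), import and dynamics (0.225), the TCA cycle (0.771), glycolysis (0.612) and hypoxia (0.771). The type 2 effector (adjusted p = 0.644), ILC2 identity (0.546), catecholamine (0.519), interferon (0.899), proteasome (0.106), unfolded protein (0.644), NRF2 (0.644), p53 (0.124), cholesterol (0.707), inhibitory receptor (0.455) and migration (0.771) lists did not pass. Nor did the marker lists of NK cells and ILC1 (adjusted p = 0.41), ILC3 (0.743), dendritic cells (0.741), endothelium (0.771) and erythroid cells (0.455); the other 7 marker lists could not be tested. Test and median differed in sign for the ILC3 (lower, 0.05), interferon (lower, 0.07) and NRF2 (lower, 0.03) lists.

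Further genes did not pass but kept 1 direction in all clusters or belonged to the fixed set. With clusters weighted equally, a setting that also shrinks low counts, many of these changes shrank. That value follows the first where it differs by over 1.5 times. Icos, the co-stimulator of ILC2s, went from 272 ± 15.6 to 408 ± 94.2 CPM (0.60, then 0.23, adjusted p = 0.252) and Cd27 from 73.3 ± 7.21 to 107 ± 10.8 CPM (0.55, then 0.24). The chromatin organiser gene Satb1 went from 153 ± 21.5 to 217 ± 33.9 CPM (0.52, then 0.20) and St8sia4, which makes polysialic acid, from 140 ± 7.24 to 190 ± 7.65 CPM (0.44, adjusted p = 0.0775). On the lower side, the GABA transporter gene Slc6a13 went from 78.1 ± 4.61 to 51.3 ± 7.36 CPM (-0.61, adjusted p = 0.0775) and Lgals1 from 677 ± 126 to 430 ± 139 CPM (-0.66, then -0.23). The calcium-binding gene S100a6 went from 794 ± 142 to 527 ± 162 CPM (-0.59, then -0.16) and the intermediate filament gene Vim from 830 ± 126 to 583 ± 109 CPM (-0.51, then -0.18). Klrg1 went from 143 ± 2.92 to 108 ± 5.62 CPM (-0.41, then -0.22, adjusted p = 0.107) without overlap, and Arg1 from 303 ± 50.6 to 219 ± 46.9 CPM (-0.47, then -0.24, adjusted p = 0.398) without overlap. Il5 went from 473 ± 105 to 683 ± 120 CPM (0.54, then 0.20, adjusted p = 0.398) and Il13 from 321 ± 49 to 357 ± 57.3 CPM (0.16, then 0.01). Areg went from 1416 ± 159 to 1522 ± 120 CPM (0.11, then -0.04) and Gata3 from 799 ± 27 to 957 ± 143 CPM (0.27, then 0.12, adjusted p = 0.491). Mki67 had a UMI in 4.30% of IL-33 cells and 2.22% of IL-33 plus dopamine cells (exact Clopper-Pearson 95% intervals 3.70 to 4.97 and 1.78 to 2.73, counting error only), and its CPM did not pass (-0.90, then -0.45, adjusted p = 0.447). In the middle percentiles of UMIs, Klrg1 was at -0.22, Mki67 at -0.50, Il13 at 0.34 and Areg at 0.18. Without hashtag 8, Icos was at 0.36, Gata3 at 0.11, Areg at 0.05 and Mki67 at -0.58, and without hashtag 7 Mki67 was at -1.51 and Il13 at 0.04. Without hashtags 3, 5 and 6, Il13 was at 0.06, 0.28 and 0.28 and Areg at 0.04, 0.20 and 0.19.

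**Figure D3:**
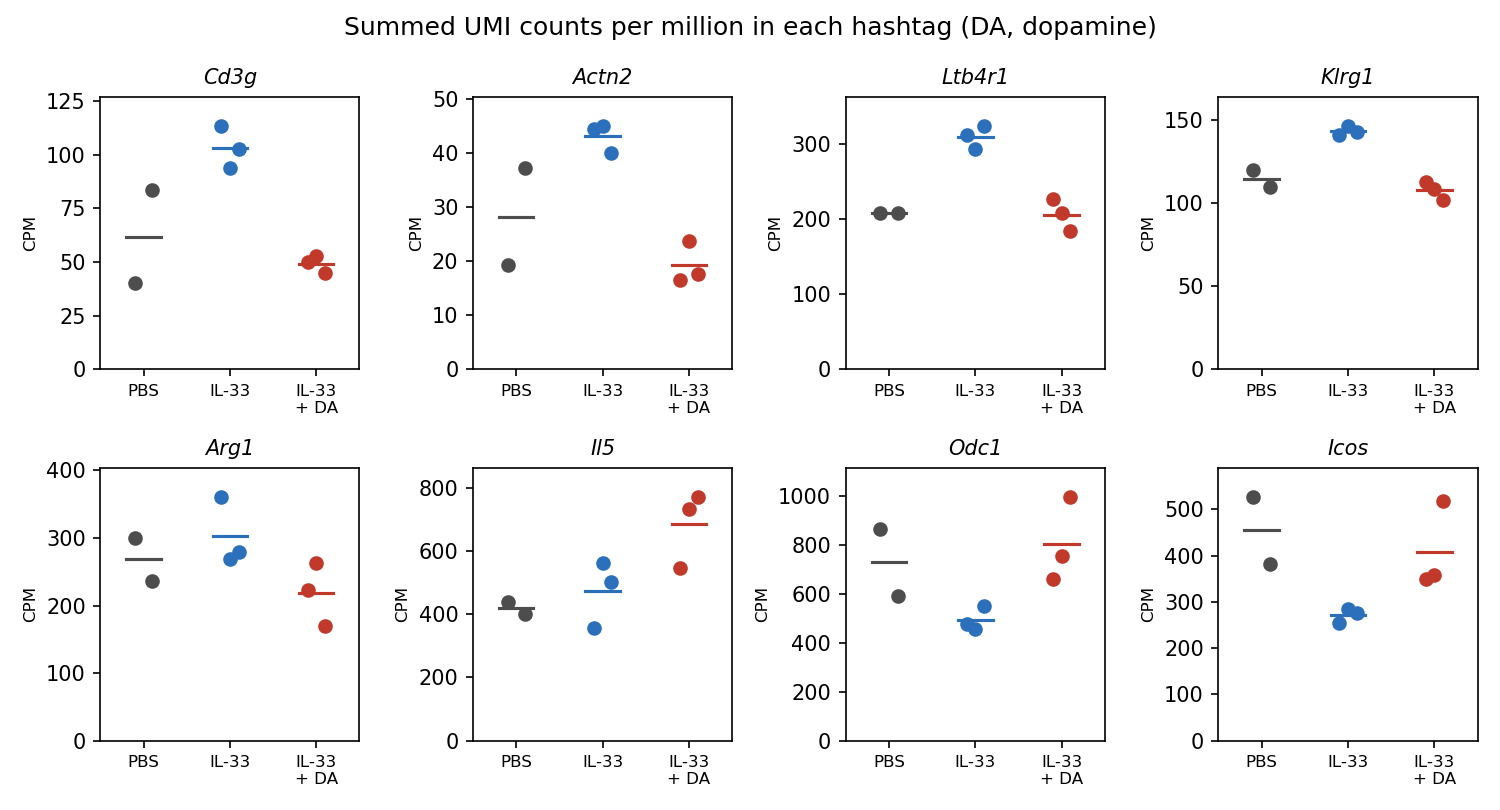
CPM of 8 genes in each hashtag, a point per hashtag and a line at the mean, for PBS (2 hashtags), IL-33 (3) and IL-33 plus dopamine (3). Cd3g, Actn2, Ltb4r1, Klrg1 and Arg1 were lower in each dopamine hashtag than in each IL-33 hashtag, and Odc1 and Icos were higher.

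Within the authors' clusters, the genes that passed with dopamine included cytokine, adhesion and division genes. All 32 calls kept their direction with each hashtag left out, but only 5 passed each time: Itgae in cluster 5, Csf2 and Egr1 in cluster 4, and 2 leading genes of their clusters. In cluster 0, Il5 rose (log2 fold change 0.69, adjusted p = 0.0192) with Odc1 (0.49, adjusted p = 0.0192); Il5 was lost without hashtag 3, 4, 5 or 6 (0.66 to 0.71 with a hashtag left out) and Odc1 without any but 6 (0.45 to 0.56). In cluster 1, Enah, an actin elongation factor gene, fell (-1.40, adjusted p = 0.0075), as did Ptgs2, the prostaglandin synthase gene (-1.62, adjusted p = 0.0465), while the heat-shock gene Hspa1a rose (1.14, adjusted p = 0.0075). Enah was lost without hashtag 5 or 7 (-1.49 to -1.32), Hspa1a without 5, 6 or 7 (0.999 to 1.296) and Ptgs2 without any 1 of the 6 (-1.77 to -1.43). In cluster 4, which heat-shock genes lead, Klf4 rose (0.64, adjusted p = 0.0113) and Csf2 (-0.75, adjusted p = 0.003) and Egr1 (-0.98, adjusted p = 0.0084) fell; Klf4 was lost without hashtag 3, 4 or 7 (0.55 to 0.77). In cluster 5, led by Il1r2, Irf4 and Ctla4, Itgae (2.47, adjusted p = 0.00048), the type 2 cytokine gene Il4 (0.91, adjusted p = 0.0385), Ramp3, a partner of the receptor for calcitonin peptides (0.96, adjusted p = 0.00051), and Alcam (1.19, adjusted p = 0.0077) rose. The mitotic genes Cenpf (-1.93, adjusted p = 0.0381) and Cenpe (-1.88, adjusted p = 0.0347) fell there, as did Plin2 (-1.04, adjusted p = 0.0119) and Zfp36 (-0.79, adjusted p = 0.0056). Except for Itgae, each of these calls in cluster 5 was lost without hashtag 7, which left 1 gene. Others were lost too: Il4 without hashtag 3, 4 or 5 (0.628 to 1.124), Alcam without 5 (1.15 to 1.21), Cenpf and Cenpe without 4, 5 or 6 (-2.50 to -1.64 and -2.26 to -1.63), and Plin2 without 5 (-1.44 to -0.65).

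Lists within clusters passed by camera in 5 of the 6 clusters, 1, 4, 2, 0, 1 and 9 lists in clusters 0 to 5, none with an estimated correlation. Lists that hold a leading gene of the cluster are not described. Type 2 effector genes were lower in cluster 2 (median -0.163 relative to all genes, adjusted p = 3.6e-05) and passed there without each hashtag. In clusters 0, 1 and 4 they did not pass, and the test pointed higher in cluster 0. Complex IV genes were lower in cluster 5 (-0.138, adjusted p = 0.0026) without each hashtag too, and complex V genes (-0.0830, adjusted p = 0.0152) lost the call without hashtag 5 or 8 (adjusted p = 0.0854 and 0.148) and had a median of -0.139 without hashtag 3 and -0.141 without hashtag 7. Cytosolic ribosome genes were lower in clusters 0 (-0.0660), 1 (-0.0493), 2 (-0.0525), 4 (-0.0698) and 5 (-0.0767). In cluster 1 that call was lost without hashtag 3, 5 or 8 (adjusted p = 0.193, 0.153 and 0.409, median -0.0270 without 8) and in cluster 2 without hashtag 5 (0.0744), and the median in cluster 5 was -0.117 without hashtag 4 and -0.136 without hashtag 6. Mitochondrial ribosome genes were lower in cluster 1 (-0.107, adjusted p = 0.024) and cluster 5 (-0.106, adjusted p = 0.0289). The first call was lost without hashtag 3, 5, 7 or 8 (adjusted p = 0.204, 0.154, 0.167 and 0.337) and the second without hashtag 5, 7 or 8 (0.229, 0.178 and 0.179, medians -0.0151, -0.0407 and -0.0876). Immediate early genes were higher in cluster 1 (0.0655, adjusted p = 0.0077), with a median of 0.178 without hashtag 5 and 0.248 without hashtag 7, and lost the call without hashtag 3 (0.123, adjusted p = 0.103) or 8 (-0.0189, adjusted p = 0.622). In cluster 5, p53 genes (0.161, adjusted p = 0.0026; 0.273 and 0.0657 without hashtags 3 and 5) and MYC and mTORC1 genes (0.235, adjusted p = 0.0098; 0.0453, not passing, without hashtag 7) were higher.

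The calls numbered 3, 6, 4 and 19 in clusters 0, 1, 4 and 5, 32 in total. In clusters 2 and 3 edgeR passed 0 genes, with 417 and 350 at an unadjusted p under 0.05; no other tool was run there. The total moved to 11 without hashtag 7 and to 112 without hashtag 8. Cluster 0 had 0 calls without hashtag 3, 0 without hashtag 4 and 10 without hashtag 8, and cluster 1 had 3, 1, 3, 1 and 24 without hashtags 3, 5, 6, 7 and 8. Cluster 2 had 8, 4 and 4 without hashtags 5, 6 and 8, cluster 3 had 2, 1, 1, 1 and 7 without hashtags 4 to 8, and cluster 4 had 8 and 17 without hashtags 5 and 8. In cluster 5, where hashtag 8 held 26 cells, 30 genes passed without hashtag 3, 7 without hashtag 5, 1 without hashtag 7 and 50 without hashtag 8. Whether a change differed between clusters was not tested. Cluster 0 held 20.4% ± 4.14 of the cells of an IL-33 hashtag and 28.6% ± 2.89 with dopamine (n = 3 each, exact permutation p = 0.1). The share of cluster 1 is left out, because its leading genes Actn2 and Cd3g passed between the treatments and may set which cells fall in it. The shares of clusters 2, 3, 4 and 5 overlapped between the groups. Cluster 2 held 15.3% ± 1.61 and 20.5% ± 5.74 (exact p = 0.2) and cluster 3 held 9.92% ± 2.1 and 16.2% ± 4.39 (exact p = 0.2). Cluster 4 held 13.1% ± 1.40 and 10.8% ± 5.67 (exact p = 0.6) and cluster 5 held 14.2% ± 6.91 and 7.56% ± 6.26 (exact p = 0.4), or 8.50% and 5.21% among cells between the 10th and 90th percentile of UMIs. The difference in cluster 4 turned from -2.29 to 0.063 percentage points without hashtag 7, and was -5.43 without hashtag 6 and -1.50 without hashtag 8. That in cluster 2 moved from 5.15 to 1.96 points without hashtag 8, and that in cluster 5 from -6.66 to -2.75 without hashtag 3 and -3.76 without hashtag 8.

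Bulk and single-cell tests pointed the same way for most lists called in bulk. They pointed opposite ways for the T cell, ILC3, mitochondrial DNA-encoded and inhibitory receptor lists, of which only the T cell list passed in the single cells. The inhibitory receptor list had a median of -0.62 in bulk and 0.22 in the single cells. Of the 20 lists called in bulk, 16 had the same direction in the single cells and 8 were called in both. Proliferation, mitochondrial ribosome, cytosolic ribosome and fatty acid lists were lower in both, and cAMP, immediate early and NF-kB lists higher in both; of these 7 only the cytosolic ribosome and NF-kB lists passed in the single cells with clusters weighted equally. The T cell list was higher in bulk and lower in the single cells. Odc1 went from 53.8 ± 44.7 to 234 ± 86.6 TPM in bulk (1.86, range 0.98 to 2.52) and from 494 ± 50.9 to 803 ± 173 CPM in the single cells. Ltb4r1, Lgals1, S100a6 and Vim were lower without overlap in bulk (relative log2 fold changes -1.57, -1.32, -1.10 and -1.01, the last 2 with ranges of -1.34 to -0.36 and -1.12 to -0.31) and lower in the single cells (-0.59, -0.66, -0.59 and -0.51), where clusters weighted equally gave -0.43, -0.23, -0.16 and -0.18. The nuclear respiratory chain lists tested lower in both, but in the single cells they did not pass and their medians were small, at -0.003 for complex I and -0.06 for complex IV. Ndufa11 went from 78 ± 3.99 to 80.3 ± 3.71 CPM and Cox8a from 684 ± 44.3 to 664 ± 60.3 CPM. Across 9533 genes, which are not independent replicates, the fold changes had a Spearman correlation of 0.187 and a Pearson correlation of 0.173; leaving out hashtag 8 gave a Spearman correlation of 0.117. Of the 4 genes called in bulk, 0 were tested in the single cells.

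**Figure D4:**
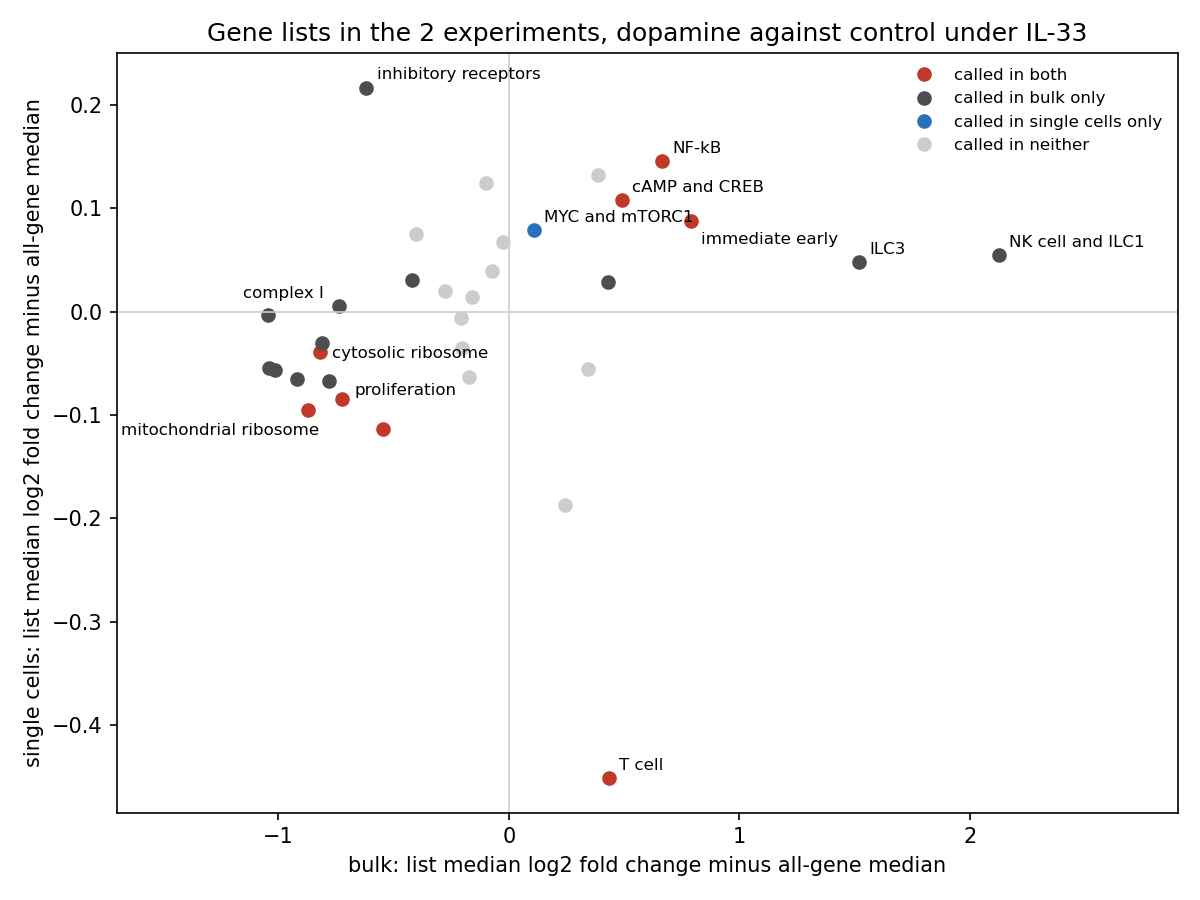
Median log2 fold change of each gene list minus that of all genes, bulk libraries on the x axis and single cells on the y axis, with a point per list tested in both, coloured by which camera tests passed. The T cell list lies at 0.43 in bulk and -0.45 in the single cells, and the y axis spans far less than the x axis.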

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

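The tests against the single-cell difference and against a rise of all other cell types were chosen after the results were seen, as were the counts over other splits of the libraries, apart from that within clusters; the number of detected genes as a covariate was added after the data were seen. Among 143 named genes tested in both experiments, 4 moved in opposite directions in bulk and in the single cells, with no overlap between the groups in either and the same direction in all settings. Actn2 was higher with dopamine in bulk (relative log2 fold change 0.99, range 0.19 to 1.53) and lower in the single cells (-1.16). Cd3e was higher in bulk (2.45, range 1.01 to 3.41) and lower in the single cells (-1.01). Zfp36 was higher in bulk (1.43) and lower in the single cells (-0.31), and Pdcd1 was lower in bulk (-1.30, range -1.40 to -0.85) and higher in the single cells (0.37). Cd3g was also higher without overlap in the deposited TPM of the bulk libraries and lower in the single cells (-1.07), but relative to all genes its bulk change was 0.07 and turned negative in 5 settings, down to -0.252. The difference between the experiments was not tested. Sex, platform and the handling of the cells differ between them together, so these cannot be separated.

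The lower respiratory chain lists in bulk could come from dopamine, from transcript features or from libraries that caught fewer genes. None of 10000 random lists matched on length, GC content and expression had a median as low (0 lists; -0.55 against a lowest of -0.42), which argues against those trends as the whole cause; for the cytosolic ribosome 49 lists did, but matching reached a mean log2 level of only 10.5 against 11.8, which keeps that question open. With the number of genes at TPM of at least 1 as a covariate, the difference shrank from -0.94 (95% interval -1.65 to -0.24) to -0.41 (-0.88 to 0.05). For the cytosolic ribosome the difference shrank from -0.81 to -0.15. What that number reflects, lowest in PBS library 2, may carry much of the difference. The number itself parts the groups and depends on how TPM is shared among genes, so the fit cannot single out library yield. Genes above 0 TPM numbered 13168 ± 587 with PBS and 13410 ± 419 with dopamine (n = 3 each, exact permutation p = 0.6). In the single cells the difference was -0.03, with a lower 95% bound of -0.132, so an effect of the bulk size was not present there. A dopamine effect specific to the bulk mice, which were female, stays open and untested.

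The T, NK and ILC3 transcripts that were higher in bulk could come from a lower purity of the sorted cells, from T and NK cells in particular, or from ILC2s that transcribe more of these genes. If a lower share of ILC2s came with more of every other cell type alike, macrophage and NK cell markers would rise together. The upper quartile of the macrophage and monocyte list (0.793, highest gene at 228 TPM) lay below the lower quartile of the NK cell and ILC1 list (1.76, highest gene at 273 TPM). This argues against an even rise for that list, on 6 macrophage genes, but cannot test a gain of lymphocytes alone. The macrophage list mean relative to all genes was 1.62, -0.417 and -0.277 in PBS libraries 1 to 3. It was 2.24 in dopamine library 2, above all PBS libraries, and -1.23 and -1.47 in dopamine libraries 1 and 3, below all of them. The argument thus rests on dopamine libraries 1 and 3, and an even rise stays open for dopamine library 2. Dopamine library 2 also had the highest T cell (1.68), NK cell (1.36) and ILC3 (1.92) means. The lower quartiles of the T cell list (0.0554) and the ILC3 list (0.599) lay within the macrophage range, and the B cell list, which did not pass, had a median of 0.99 and an upper quartile of 1.17. An even rise of all other cell types stays open for the T cell and ILC3 transcripts. A lower share of ILC2s with more lymphocytes stays open for the NK cell transcripts as well. Of 13 further T and NK transcripts written down before they were looked up, 69.2% lay above the median of all genes and 4 were higher without overlap, which lies between what T and NK cells and their absence would give. Sorts of ILC2s commonly exclude cells with CD3 or NK1.1, but the labels give no gate. T and NK cells among the sorted cells and a change in the ILC2s themselves cannot be told apart here.

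Splits of 3 against 3 samples number 10, too few for a share under 0.05. The real split gave 4 genes in bulk and the highest other 2, with 1 split as large, the real one included. For bulk lists these were 20 and 19 (1 split as large), for single-cell genes 3 and 0 (1 split), for single-cell lists 9 and 13 (3 splits as large), and for genes called within clusters 32 and 23 (1 split). The other bulk splits called 19, 19, 17, 14, 10, 9, 8, 1 and 0 lists. They mix the treatments unevenly and so keep part of the contrast. With camera at the preset correlation, the number of lists called therefore does not set dopamine apart from other groupings of the samples.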

How the results depend on the processing

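Alternatives for IL-33 against PBS, the estimated correlation and fry in the single cells, the leaving out of hashtags for lists within clusters, and the removal of length, GC and expression trends were chosen after the data were seen. Of 20 bulk lists 20 kept the direction of their test in all settings, and 0 kept their side of the threshold, since none passed with the estimated correlation; of 9 single-cell lists 8 kept their direction. Within clusters, 17 called lists and 32 called genes all kept the direction of their test, and 0 and 5 kept their side. The median of the bulk NRF2 list relative to all genes turned to 0.0177 with trends removed, while its test stayed lower. Of 102 named bulk genes 97 kept their direction relative to all genes, as did 51 of 54 single-cell genes. The cause of the changes that follow was not tested, except that a smaller design or a stricter filter tests fewer samples or genes. Bulk genes passing (4) became 2 with a pseudocount of 5, 0 without a filter (2712 at an unadjusted p under 0.05 by limma), 2 at a mean TPM of at least 5, 21 with quantile normalization, 15 in the fit with replicate number as a block, which kept 20 lists, and 2800 with array weights. They ranged from 0 to 1536 with a library left out. Bulk lists (20) became 0 with an estimated correlation and 0 with fry, with a range from 15 to 21 with a library left out. Single-cell genes (3) became 8 in cells between the 10th and 90th percentile of UMIs, 6 in thinned cells, 1 with clusters weighted equally and 27 by DESeq2, and ranged from 1 to 16 with a hashtag left out. Single-cell lists (9) became 3 with clusters weighted equally, 0 with an estimated correlation and 1 with fry. IL-33 against PBS (74 genes, 11 lists) gave 119 genes by DESeq2, 5 to 124 genes and 5 to 10 lists with a hashtag left out, and 0 lists with an estimated correlation or fry. Calls within clusters (32) ranged from 11 to 112. The share of cluster 4 ranged from -5.43 to 0.063 percentage points. The Spearman correlation between experiments (0.187) was 0.319 over 3799 well-covered genes and 0.117 to 0.236 with a sample left out. The single-cell immediate early list ranged from -0.0157 to 0.227 with a hashtag left out, negative without hashtag 8. In bulk, Fth1 (relative log2 fold change -0.02) turned to 0.18 with a pseudocount of 5, 0.21 without a filter, 0.66 with quantile normalization, 0.44 with trends removed, and ranged from -0.253 to 0.115 with a library left out, above 0 without PBS library 2 or 3 (0.115, 0.106) or dopamine library 1 or 3 (0.00343, 0.0552). Il1rl1 (-0.21) turned to 0.0162 without a filter, 0.0462 with quantile normalization and 0.32 with array weights, and ranged from -0.524 to 0.173 with a library left out, above 0 without PBS library 1 (0.173) or dopamine library 2 (0.0484). Mki67 turned to 0.20 with array weights, mt-Co1 to 0.0381 and CT010467.1 to -0.0156 with quantile normalization, and CT010467.1 ranged from -0.0381, without PBS library 1, to 0.285 with a library left out. In the single cells, Areg turned to -0.0391 and Tnfrsf9 to -0.00696 with clusters weighted equally, and mt-Co1 to 0.00418 in the middle percentiles. Coarser cluster labels and a block by mouse number were not run, since the cell table holds neither. In the single cells 7 lists had fewer than 3 members with enough counts to be tested; whether depth or absence from these cells was the reason was not tested.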

Other observations

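IL-33 against PBS in the single cells and the shared-control tests were chosen after the data were seen; those without hashtag 8 and with clusters weighted equally had their bounds set before they were run. The PBS hashtags, which the sample labels do not mention, show what IL-33 alone did to lung ILC2s. By edgeR 74 of 10506 genes passed, 37 higher and 37 lower, and 1411 had an unadjusted p under 0.05; the count was 5 without hashtag 1, 40 without hashtag 3 and 124 without hashtag 4. Without hashtag 2 it was 72, but 11 higher and 61 lower, of which 28 were among the 74; without TMM it was 74, 45 higher and 29 lower. Division genes rose: Ccnb2 went from 0.298 to 6.29 ± 0.398 CPM (log2 fold change 3.80, adjusted p = 0.00842), Mki67 from 3.19 to 10.4 ± 2.02 CPM (1.88, adjusted p = 0.0373) and Stmn1 from 11.8 to 23.9 ± 1.78 CPM (0.93). In PBS hashtags 1 and 2, Ccnb2 stood at 0 and 0.596 CPM and Mki67 at 4.29 and 2.08 CPM. Levels this low make the size of these fold changes uncertain. Hashtag 1 also lay apart, with a first principal component score of -46.0 against -2.02 to 12.7 in the other hashtags. Other genes that rose were the growth factor gene Csf2 (0.58, adjusted p = 0.0127), Areg from 1005 to 1416 ± 159 CPM (0.46, adjusted p = 0.0235), Lgals1 from 385 to 677 ± 126 CPM (0.76), Vim from 480 to 830 ± 126 CPM (0.75) and Ltb4r1 from 208 to 310 ± 16 CPM (0.54, adjusted p = 0.00822). Icos fell from 455 to 272 ± 15.6 CPM (-0.76, adjusted p = 0.00684), as did the transcription factor genes Lmo4 (-0.68), Cebpb (-0.66), Atf3 (-0.84) and Fosb from 2029 to 1560 ± 113 CPM (-0.42). Camera placed 11 of 34 lists past the threshold: type 2 effectors (adjusted p = 0.0029), proliferation, mitochondrial ribosome, proteasome and dendritic cell genes higher, and immediate early, ILC2 identity, cAMP, MYC, mitochondrial DNA-encoded and NK cell genes lower, none of them with an estimated correlation (adjusted p of at least 0.751).

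Most of these genes had opposite signs in the 2 comparisons, although 1 of the 74, Ltb4r1, passed in both. Of the 37 genes that rose with IL-33, 35 were lower with dopamine, and of the 37 that fell, 34 were higher, 93.2% in all, against 82.8% on average and 91.9% at most in simulations with no dopamine effect, where the shared IL-33 hashtags alone create such a pattern. Lgals1, Vim, Stmn1, Ccnb2, Icos and Klf4 had opposite signs but did not pass with dopamine. Over 2492 genes with CPM of at least 50, the changes of dopamine and of PBS relative to IL-33 had a covariance of 0.0213, above all simulations (0.00459 to 0.00704), and 0.0126 without hashtag 8. Another labelling of the same hashtags reached 0.0191, which is also above all simulations. The simulations therefore cannot exclude the shared control or hashtag 8 as the source. With clusters weighted equally the covariance was 0.00835, so a shift of cells between clusters may carry a large part and cannot be told apart from a change within cells. The 20 ways to label the hashtags are too few for a share under 0.05 (real value 0.0213, highest other 0.0191).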
